A study of Mus musculus with 12 samples.

How the data were processed

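The data are array measurements of liver RNA from 12 samples of mice on a mixed C57BL/6J and 129 background. Per the labels, mice with a hepatocyte-specific deletion of FoxO1, FoxO3 and FoxO4 and age- and sex-matched littermate controls were kept with 4 to 5 animals per cage and a 12 h light and dark cycle. They were fasted for 22 h or refed for 4 h. Total RNA was isolated with Trizol and labelled with a Nugen kit, per the labels' protocols. The deposited values are log2 signals, which per the submitters' processing notes came from RMA in Partek. The versions and the exons removed are not given in the sources used here.

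The table held 23238 transcript clusters, 0 missing values and 0 unused columns of values, and 0 pairs of arrays were identical. A gene symbol was paired with 14939 clusters by the probe table, 989 had several symbols and 7310 had none there. The Entrez identifiers of 14884 of the 14939 were found in a RefSeq gene table, which changed 0 symbols. For the 131 genes with more than 1 cluster, the cluster with the highest mean over the 12 arrays was used, which left 14807 genes. Clusters with several symbols or none were left out of the tests and looked at separately. No reference genome was used here, so no positions are given. Array medians lay between 5.79 and 5.90, and 39.2% of clusters had a mean under 5 log2 units, where an array cannot separate low signal from background. The median SD within groups was 0.18 log2 units and the median SE of a comparison 0.14.

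Samples were grouped by genotype and feeding state into 4 groups of 3 arrays. Replicate numbers follow the order of deposit and are names alone. The labels give each sample its own title but do not state that each array holds 1 mouse, so p values measure the spread between these samples and the replicates may be technical in part. Comparisons came from limma 3.58.1 in R 4.3.3, with a mean per group, moderated variances, 8 residual degrees of freedom and 3.23 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were knockout against control in each feeding state, refed against fasted livers in each genotype, and the interaction. Averages of the genotype comparisons and of the feeding comparisons, 2 in all, were added after the data were seen. Figures were drawn with Python 3.11.15.

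A set of 35 gene lists, 11 of them markers of cell types, was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Camera with a correlation estimated from the arrays passed 0 lists in each comparison after adjustment, and fry was run in its 1-direction and mixed forms. Members were also counted after adjustment over all genes and adjusted over the list alone. The named genes were Foxo1, Foxo3 and Foxo4, a panel of 30 metabolic genes, the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap, and up to 4 called members of each list described, or up to 2 with the smallest p where fewer than 2 passed. Together the panel and the deleted genes came to 33, of which 27 had a cluster of their own and the others are not analysed here. The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, except where said to be chosen after.

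The size of one set of changes relative to another was the covariance across genes of the log2 changes divided by the variance of the first less its mean squared SE. The clock index was the mean of 4 clock genes (Arntl, Clock, Cry1 and Nfil3) less that of 4 others (Dbp, Tef, Per3 and Nr1d2). It was compared between genotypes by an exact permutation test over the 400 regroupings within feeding states. The steps were tested on simulated data of 14807 independent genes with 200 changed per set. In 5 sets, 80.8% of genes changed 2-fold were called for knockout against control in fasted livers, 83.6% in refed livers, 82.4% for refeeding in control and 78.8% in knockout livers, and 56.8% for the interaction. At 1.5-fold these were 40.8%, 43.6%, 47.2%, 43.2% and 18.8%. False calls made up 4.30% to 5.52% of calls over these comparisons.

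Alternatives were filters on mean signal at the 30th and 50th percentile, equal array medians, a further quantile normalization, a fit to the compared groups alone, a variance trend with robust moderation, array weights, other ways to combine clusters, the number series of the sample titles as a random block, stricter thresholds and leaving out each array in turn. The clock index as a covariate was added after the data were seen.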

Results

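RNA of mouse liver was measured in 12 samples on arrays that give 1 log2 signal per transcript cluster, a set of probes for 1 gene or transcript. The mice lacked the transcription factors FoxO1, FoxO3 and FoxO4 in hepatocytes or were littermate controls, and the livers came from mice fasted for 22 h or refed for 4 h. Each of the 4 groups of genotype and feeding state had 3 arrays. The series asks how FoxO factors steer the liver between making fat and making glucose. Array medians lay between 5.79 and 5.90 log2 units, and the number of arrays limits the precision. All 12 arrays carried male-specific transcripts, with Eif2s3y between 8.40 and 9.17 and Kdm5d between 7.10 and 7.59. Knockout refed replicate 1 stood apart, with a mean correlation across genes of 0.981 with the other arrays and a limma array weight of 0.33. Genes are not independent replicates for such a correlation.

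The deleted genes were examined first, as a check of the genotype labels. Foxo1 signal in knockout livers was 84.1% of control in the fasted state, a log2 change of -0.25 ± 0.14 (SE, n = 3 arrays per group), and 76.2% in the refed state. Foxo3 stood at 90.5% of control in fasted and 91.4% in refed livers, and Foxo4 at 89.0% and 112%. None of these 6 differences passed limma's test, with adjusted p from 0.162 for Foxo1 in refed livers to 0.906 for Foxo4 in fasted livers. The deleted exons are not given in the sources used here, other liver cells keep the genes, and a signal over a whole transcript can outlast the loss of exons, so these values check the labels only weakly.

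Knockout against control livers in the fasted state asks what FoxO factors do when glucose production is needed. Genes for protein folding in the endoplasmic reticulum rose in fasted knockout livers. Sdf2l1, which assists folding there, rose 13.2-fold, a log2 change of 3.73 ± 0.42 (SE, n = 3 arrays per group, adjusted p = 0.003). Hspa5, the main chaperone of that compartment, rose 3.72-fold (adjusted p = 0.00308) and Manf, a secreted stress-induced protein, 4.94-fold (adjusted p = 0.00203). The cytosolic chaperone gene Hsph1 rose 4.74-fold (adjusted p = 0.00902). Among the genes that fell were Txnip, which restrains glucose uptake, 2.74-fold lower at a log2 change of -1.46 ± 0.15 (adjusted p = 0.00203), and Angptl4, an inhibitor of lipoprotein lipase, 3.25-fold lower at -1.70 ± 0.28 (adjusted p = 0.0142).

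Of the 21 measured genes of the unfolded protein response, 10 rose, 11 did not pass, and all 21 had a positive change in fasted knockout livers. Adjusted over the list alone, 18 rose and 0 fell. Other members that rose were Hyou1 (log2 change 2.34 ± 0.28), Creld2 (2.94 ± 0.38), Derl3 (2.98 ± 0.53) and Pdia4 (1.30). The list rose as a set by limma's camera, with a median log2 change of 0.92 (adjusted p = 1.64e-24, and adjusted p = 0.307 with an estimated correlation). Beside this list, an index of clock genes, the mean of Arntl, Clock, Cry1 and Nfil3 less that of Dbp, Tef, Per3 and Nr1d2, was -3.15 ± 0.46 (SD) in the 6 control arrays and -2.12 ± 0.76 in the 6 knockout arrays (exact permutation p = 0.01, 2-sided, within feeding states). Knockout fasted replicate 3 (-1.25) and knockout refed replicate 3 (-1.24) stood highest, followed by knockout refed replicate 2 (-2.05). The titles of these arrays share a number series. The other knockout arrays lay from -3.08 to -2.37 and the control arrays from -3.49 to -2.23. Ribosome biogenesis genes also rose as a set, with a median of 0.42 over 22 genes (adjusted p = 5.91e-08, and 0.7 as adjusted p with an estimated correlation). By limma 0 of these 22 passed over all genes and 9 rose adjusted over the list alone, with Bop1 at 0.53 (adjusted p = 0.0518) and Mybbp1a at 0.62 (adjusted p = 0.0539), both of which act in making ribosomal RNA.

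A list of genes associated with FoxO factors is called FoxO-driven here for short, without a claim that each is a direct target. These genes fell as a set in fasted knockout livers, with a median log2 change of -0.24 over 32 genes (adjusted p = 3.35e-06 by camera, and adjusted p = 0.307 with an estimated correlation). Of these, 4 fell, 0 rose and 28 did not pass. Adjusted over the list alone, 8 fell and 1 rose. The 4 were Txnip, the cell cycle inhibitor Ccng2 (-1.56 ± 0.29, adjusted p = 0.021), the growth factor receptor gene Erbb3 (-0.91 ± 0.19, adjusted p = 0.0383) and Fbxo32, a ubiquitin ligase of muscle wasting (-0.45 ± 0.09, adjusted p = 0.031). Igfbp1, an insulin-repressed binding protein for growth factors, was at -2.01 ± 0.58 and did not pass (adjusted p = 0.134). The autophagy list had a median of -0.08 (adjusted p = 0.0454, and adjusted p = 0.7 with an estimated correlation), and 1 of its 22 genes, the autophagosome component Map1lc3b, fell (-0.57 ± 0.11). Klhl24 (-1.54 ± 0.16), the uridine phosphorylase gene Upp2 (-1.87 ± 0.23) and Ppm1k (-1.53 ± 0.27), which activates breakdown of branched-chain amino acids, fell as well.

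Few genes of glucose and fat metabolism passed the test in fasted knockout livers. Elovl6, which lengthens fatty acids, rose 2.65-fold (1.41 ± 0.25, adjusted p = 0.019) and was the 1 called gene of 24 measured lipogenic genes (list adjusted p = 0.334). Fasn, which makes palmitate, was at 0.90 ± 0.30 (adjusted p = 0.197), and Srebf1, a regulator of lipogenesis, at -0.07 ± 0.30 (adjusted p = 0.975). Pck1 and G6pc, key enzymes of glucose production, were at -0.85 ± 0.33 (adjusted p = 0.291) and -0.86 ± 0.42 (adjusted p = 0.432), and 0 of 14 gluconeogenic genes passed limma's test (list adjusted p = 0.111). The fatty acid oxidation list fell, with a median of -0.21 over 23 genes, 22 of them negative (adjusted p = 0.000117, and adjusted p = 0.7 with an estimated correlation), and 1 of them, Angptl4, was called singly. Of the 11 marker lists of cell types, only those of lymphocytes and Kupffer cells passed camera at the preset correlation. The lymphocyte list, whose array means of 4.72 to 5.33 lie near background, was lower, with a median of -0.30 (adjusted p = 0.000199, and adjusted p = 0.619 with an estimated correlation), and the Kupffer cell list at -0.28 (adjusted p = 0.0138, and adjusted p = 0.7 with an estimated correlation). Hepatocyte markers had a median of -0.05 (adjusted p = 0.388).

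By limma, 157 genes were higher and 52 lower in fasted knockout livers, 209 of the 14807 tested (1915 at an unadjusted p under 0.05, against 740.4 from chance). All 209 separated the 3 knockout from the 3 control arrays, as did 19.2% of all genes against 10% from chance. The 1-direction form of fry, limma's rotation test, which does not compare a list with other genes, passed 2 lists, the unfolded protein response (adjusted p = 0.0144) and FoxO-driven genes (adjusted p = 0.0353). Of the 24 named genes called, 12 stayed called without each array in turn. Elovl6 reached an adjusted p of 0.0812, Angptl4 0.0525 and Ccng2 0.0928, and the count became 82 without control replicate 1, 87 without control replicate 3, 113 without knockout replicate 1, 90 without knockout replicate 3 and 317 without knockout refed replicate 1. With the clock index as a covariate, a setting chosen after the data were seen, the count was 60. The Kupffer cell call was lost without control replicate 2 (adjusted p = 0.147), knockout replicate 2 (0.068) or knockout replicate 3 (0.0513), and the autophagy call without control replicate 2 (0.0907), control replicate 3 (0.181), knockout replicate 2 (0.0931), knockout replicate 3 (0.0636) or control refed replicate 2 (0.0548).

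**Figure D1:**
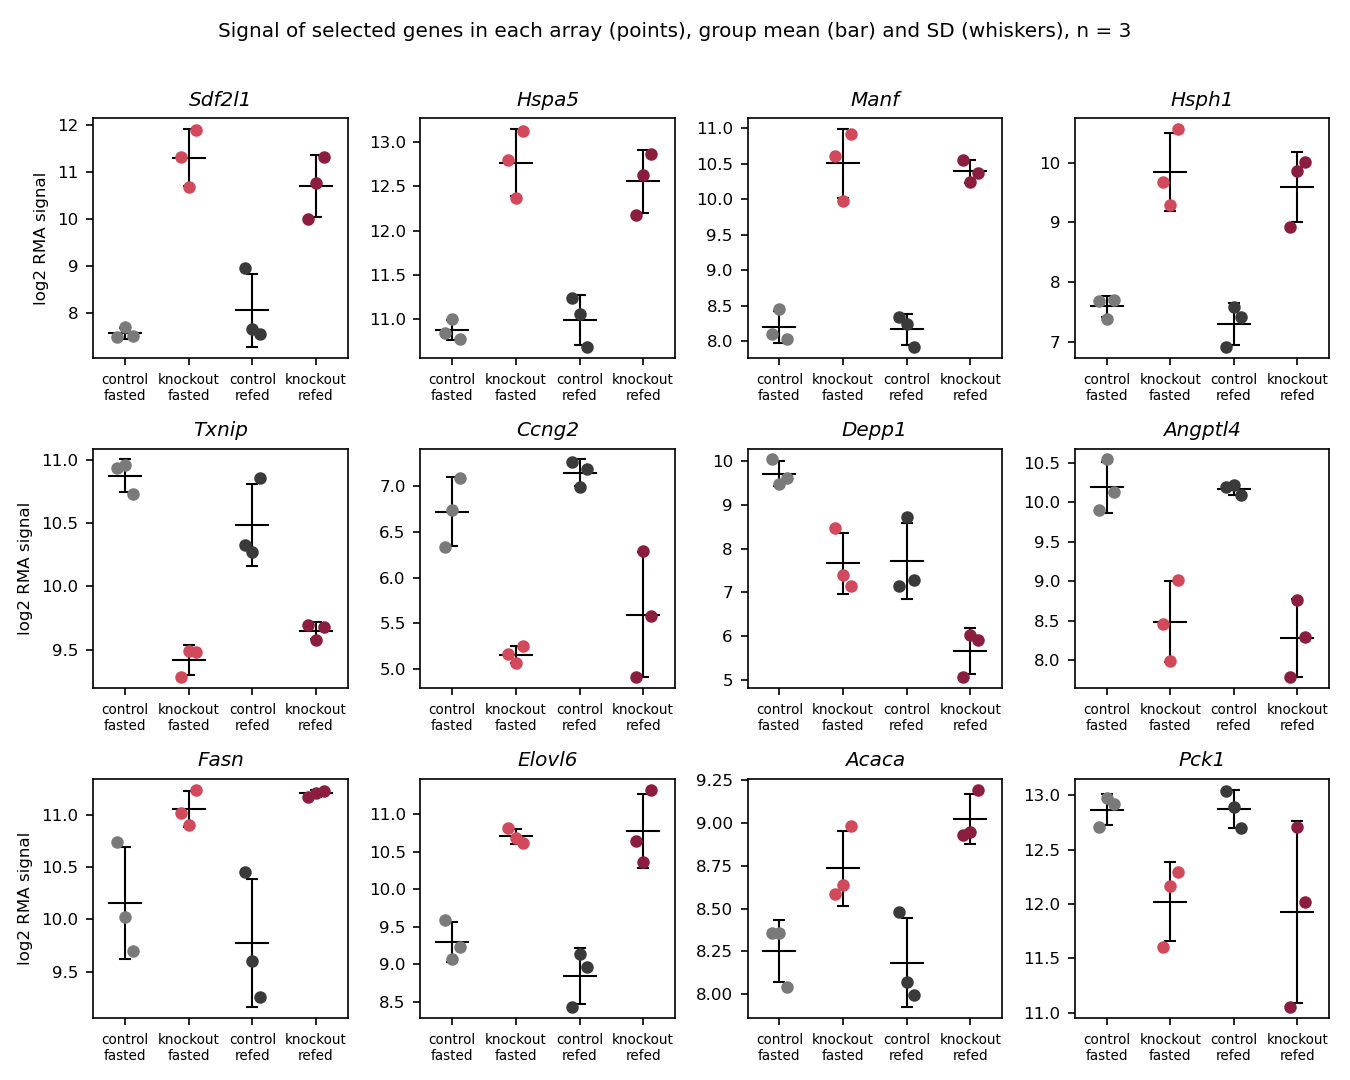
Log2 signal of 12 named genes in each array, by genotype and feeding state, with 1 point per array, a bar at the mean and whiskers of 1 SD (n = 3 arrays per group). Sdf2l1, Hspa5, Manf and Hsph1 sit higher and Txnip, Ccng2, Depp1 and Angptl4 lower in knockout arrays of both feeding states.

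The same comparison in the refed state asks what FoxO factors do when fat synthesis is favoured. A group of 4 genes of fat synthesis rose in refed knockout livers. Elovl6 rose 3.82-fold (1.93 ± 0.25, n = 3 arrays per group, adjusted p = 0.00842), Fasn 2.69-fold (1.43 ± 0.30, adjusted p = 0.0446), and Acaca, which makes malonyl-CoA, 1.79-fold (0.84 ± 0.16, adjusted p = 0.0353). Among the genes that fell were Ppara, the regulator of fatty acid oxidation, 1.75-fold lower at -0.80 ± 0.16 (adjusted p = 0.0373), and the lipid droplet coat gene Plin2, 2.14-fold lower at -1.10 ± 0.24 (adjusted p = 0.0478). Rab30, a small GTPase of membrane traffic, was 4.33-fold lower at -2.11 ± 0.17 (adjusted p = 0.000854).

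Of 24 measured lipogenic genes, 4 rose, 0 fell and 20 did not pass in refed knockout livers. Adjusted over the list alone, 6 rose and 4 fell. The fourth was Mid1ip1, which activates acetyl-CoA carboxylase (1.12 ± 0.24). The list's median was -0.16 and its mean 0.12, and camera placed it on the higher side without passing (adjusted p = 0.411). Srebf1 was at -0.34 (adjusted p = 0.617) and Scd1, the stearoyl-CoA desaturase, at -0.47, both without a call. The fatty acid oxidation and ketogenesis list fell, with a median of -0.67 over 23 genes (adjusted p = 3.38e-09, and adjusted p = 0.815 with an estimated correlation). All 23 had a negative change, 4 fell over all genes, and 17 fell adjusted over the list alone. Beside Ppara, Plin2 and Angptl4 (-1.88 ± 0.28), the carnitine carrier gene Slc25a20 fell (-1.12 ± 0.23). Sterol synthesis genes rose as a set, with a median of 0.68 over 18 genes, 16 of them positive (adjusted p = 9.71e-07, and adjusted p = 0.815 with an estimated correlation). By limma 0 of them passed singly, with Sqle, an early enzyme of the pathway, at 1.73 ± 0.70 (adjusted p = 0.213). The sterol list's array means were 10.18, 9.35 and 8.83 in refed control replicates 1, 2 and 3. In refed knockout replicates 1, 2 and 3 they were 9.93, 10.36 and 10.13, so the groups overlapped. The list kept its camera call without each array, with a highest adjusted p of 0.0039 without refed control replicate 3.

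Genes of glucose production were lower as a set in refed knockout livers, with a median of -0.40 over 14 genes (adjusted p = 0.0239, and adjusted p = 0.815 with an estimated correlation). By limma 0 of the 14 passed singly. Pck1 was at -0.95 ± 0.33 (adjusted p = 0.157) and G6pc at 0.04 ± 0.42 (adjusted p = 0.983). The FoxO-driven list fell, with a median of -0.31 (adjusted p = 0.00675, and adjusted p = 0.815 with an estimated correlation), and 4 of 32 genes fell, 11 when adjusted over the list alone. They were Txnip (-0.83 ± 0.15), Ccng2 (-1.55 ± 0.29), the insulin receptor gene Insr (-0.52) and Pnpla2, the lipase that starts triglyceride breakdown (-0.70). Unfolded protein response genes rose again, with a median of 0.84 (adjusted p = 3.57e-17, and adjusted p = 0.789 with an estimated correlation). Of the 21, 8 rose and 13 did not pass, and adjusted over the list alone 14 rose and 1 fell. Sdf2l1 rose 6.22-fold (2.64 ± 0.42, adjusted p = 0.0235) and Hspa5 2.96-fold (1.57 ± 0.22, adjusted p = 0.0136).

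Further lists passed camera in refed knockout livers at the preset correlation. Ribosome biogenesis genes were higher, with a median of 0.13 (adjusted p = 0.00428, and adjusted p = 0.871 with an estimated correlation). Kupffer cell markers were lower, with a median of -0.42 (adjusted p = 0.0229, and adjusted p = 0.818 with an estimated correlation), and Cd14, a receptor for bacterial lipid, was at -0.79 (adjusted p = 0.0605). Neutrophil markers had a median of -0.43 with 0 of 11 genes positive (adjusted p = 0.0595), and -0.06 without refed control replicate 1, whose list mean was 5.86 against 4.41 to 4.71 in the other arrays (the list passed without refed control replicate 2 and, at the lowest adjusted p of 0.00151, without refed control replicate 3). The male-biased list had a median of 0.36 (adjusted p = 0.036, and adjusted p = 0.815 with an estimated correlation), with 5 of 7 genes positive and 1 called singly, the anion transporter gene Slco1a1 (1.31 ± 0.27). Insulin and growth hormone signalling genes had a median of -0.28 (adjusted p = 0.0465, and adjusted p = 0.815 with an estimated correlation), and amino acid catabolism genes one of -0.28 (adjusted p = 0.0465, and adjusted p = 0.871 with an estimated correlation). In the latter, Bckdha, of branched-chain amino acid breakdown, fell (-0.79 ± 0.17). Hepatocyte markers had a median of -0.06 (adjusted p = 0.693). The largest falls over all genes included Olfr703 (-2.89 ± 0.46), an olfactory receptor gene, and the lipid transporter gene Mfsd2a (-1.66 ± 0.22).

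By limma, 67 genes were higher and 168 lower in refed knockout livers, 235 in all (2782 at an unadjusted p under 0.05), and each of the 235 separated the 6 arrays, as did 21.0% of all genes against 10% from chance. The 1-direction form of fry passed 4 lists, fatty acid oxidation, lipoprotein metabolism, FoxO-driven genes and the unfolded protein response (adjusted p = 0.0327 each). With the clock index as a covariate the count was 11. The lead of lower genes was lost as well, with 28 higher and 20 lower without refed knockout replicate 1, 8 and 6 without refed knockout replicate 3, and 11 and 11 without refed control replicate 2. The count depended on single arrays: it became 111, 137 and 98 without fasted control replicates 1, 2 and 3, 118 without fasted knockout replicate 2, 89, 22 and 16 without refed control replicates 1, 2 and 3, and 48, 1074 and 14 without refed knockout replicates 1, 2 and 3. Of 32 named genes called, Elovl6, Manf and Rab30 kept the call without each array in turn, while 28 lost it without refed control replicate 3 and 29 without refed knockout replicate 3, and the adjusted p reached 0.162 for Fasn, 0.152 for Acaca, 0.149 for Ppara and 0.186 for Plin2. List calls were lost without refed control replicate 1 for gluconeogenesis (adjusted p = 0.116), Kupffer cell (0.116), male-biased (0.0917), insulin signalling (0.116) and amino acid genes (0.365), without refed knockout replicate 1 for gluconeogenesis (0.117), insulin signalling (0.115) and amino acid genes (0.106), without refed knockout replicate 2 for Kupffer cell (0.0883) and insulin signalling genes (0.056), and without refed knockout replicate 3 for ribosome biogenesis, Kupffer cell, male-biased and amino acid genes (0.145 for each). Insulin signalling was also lost without refed control replicate 2 (0.106), fasted control replicates 1 (0.05), 2 (0.0547) and 3 (0.0501) and fasted knockout replicates 1 (0.0525) and 2 (0.059), and amino acid genes without fasted control replicate 2 (0.0547) and fasted knockout replicates 1 (0.0541) and 2 (0.0534).

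The genotype comparisons of the feeding states share no array and were set side by side. Both use each gene's spread over all arrays, so their calls are not independent. A count expected from independent lists can therefore be too low. Of the called genes, 39 were higher in both, against 0.71 expected from independent lists, and 31 lower in both, against 0.59, while 0 moved in opposite directions. Among those shared were Sdf2l1, Hspa5, Manf, Hsph1 and Elovl6 on the higher side and Txnip, Ccng2, Angptl4 and Depp1, an autophagy regulator, on the lower. Across all genes, which are not independent replicates, the changes correlated at r = 0.576, and the refed effect was 1.07 times the fasted effect after noise was taken out of the variance. Depp1 was 4.13-fold lower in fasted livers (-2.05 ± 0.44, adjusted p = 0.0492) and 4.15-fold lower in refed livers (adjusted p = 0.0483), and the highest adjusted p without 1 array was 0.178 and 0.154.

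**Figure D2:**
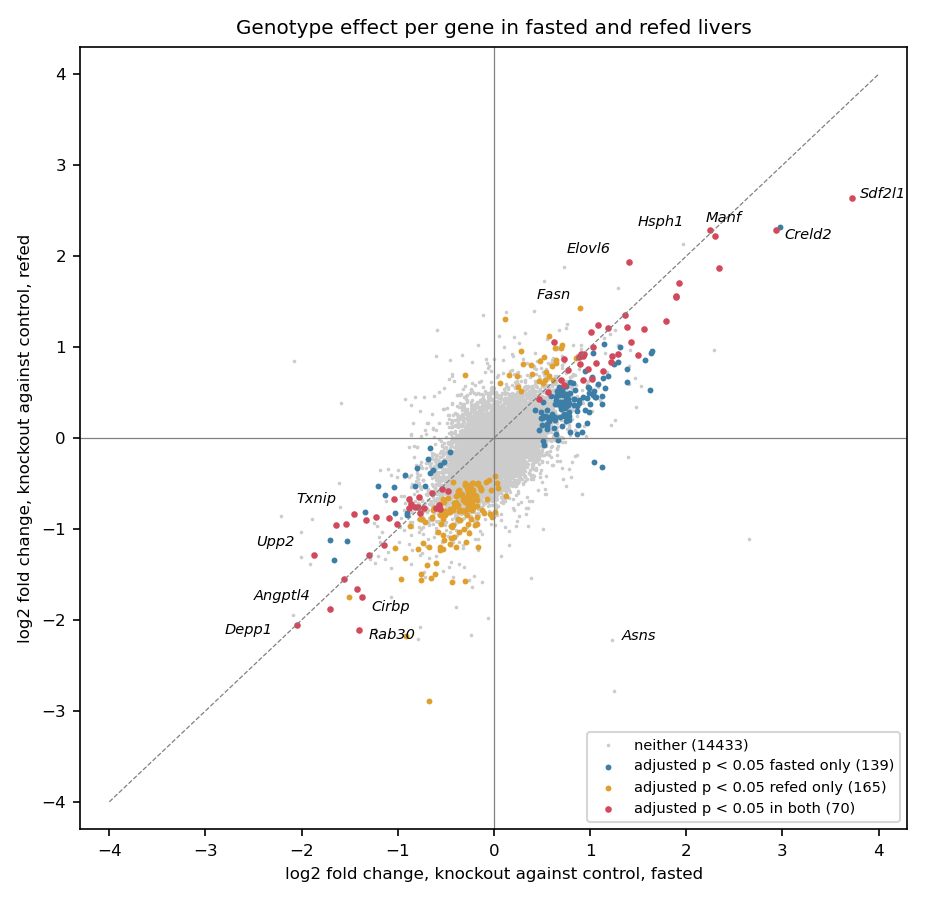
Log2 change between knockout and control livers for each of 14807 genes, in the fasted state on the horizontal axis and in the refed state on the vertical axis, with 1 point per gene coloured by where limma called it. The 70 genes called in both states lie in the upper right and lower left, 39 higher and 31 lower.

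Refed against fasted control livers shows what 4 h of food changed with FoxO factors present. By limma 4 genes passed. Slc1a4, a carrier of neutral amino acids, rose 2.24-fold (1.17 ± 0.15, n = 3 arrays per group). Slco1a4, an organic anion carrier, was 3.08-fold lower (-1.62 ± 0.20), Nox4, a producer of hydrogen peroxide, 2.28-fold lower (-1.19 ± 0.14), and the phosphate carrier gene Slc17a2 1.94-fold lower (-0.95 ± 0.13), each with an adjusted p of 0.0405. The panel of metabolic genes gave no call: Pck1 was at 0.01 ± 0.33, Srebf1 at 0.01 ± 0.30, Fasn at -0.38 ± 0.30 and Igfbp1 at -0.12 ± 0.58. The bile acid enzyme gene Cyp8b1 was at -2.93 ± 0.54 (adjusted p = 0.161) and Apom, a carrier of sphingolipid in lipoproteins, at -2.02 ± 0.32 (adjusted p = 0.0703).

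In control livers, 12 lists passed camera at the preset correlation. Sterol synthesis genes had a median of -0.46 after refeeding, with 17 of 18 negative and 0 called by limma (adjusted p = 0.000333, and adjusted p = 0.76 with an estimated correlation). FoxO-driven genes had a median of -0.11 (adjusted p = 0.00302, and adjusted p = 0.76 with an estimated correlation), bile acid genes -0.14 (adjusted p = 0.0127, and adjusted p = 0.76 with an estimated correlation), oxidative phosphorylation genes -0.11 (adjusted p = 0.00489, and adjusted p = 0.76 with an estimated correlation) and fatty acid oxidation genes 0.09 (adjusted p = 0.0244, and adjusted p = 0.76 with an estimated correlation). Acute phase genes had a median of 0.21 (adjusted p = 0.00357, and adjusted p = 0.76 with an estimated correlation), with the iron-binding Lcn2 at 2.32 and no call. Among cell markers, neutrophil genes had a median of 0.44 (adjusted p = 0.00302, and adjusted p = 0.76 with an estimated correlation), stellate cell genes 0.19 (adjusted p = 0.00357, and adjusted p = 0.76 with an estimated correlation), endothelial genes -0.22 (adjusted p = 0.00865, and adjusted p = 0.76 with an estimated correlation) and Kupffer cell genes 0.15 (adjusted p = 0.0425, and adjusted p = 0.76 with an estimated correlation). Cholangiocyte genes had a median of 0.15 (adjusted p = 0.0301, and adjusted p = 0.524 with an estimated correlation) and adipose genes 0.05 (adjusted p = 0.0301, and adjusted p = 0.524 with an estimated correlation). Refed control replicate 1 stood out for its neutrophil list mean, as given for the refed comparison of genotypes.

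Of the 4 calls, 1 was higher and 3 lower (822 genes at an unadjusted p under 0.05, and 10.7% of genes without overlap against 10% from chance). The count was 0 without fasted control replicates 1 or 2, any fasted knockout replicate or refed knockout replicate 2, 2 without fasted control replicate 3 or refed control replicate 1, 1 without refed control replicates 2 or 3, 8 without refed knockout replicate 1, and 5 without refed knockout replicate 3. FoxO-driven genes alone kept the list call without each array: without refed control replicate 1 the adjusted p was 0.261 for oxidative phosphorylation, 0.971 for acute phase, 0.658 for neutrophil, 0.658 for Kupffer cell, 0.61 for endothelial and 0.0862 for cholangiocyte genes, and without refed control replicate 3 it was 0.262 for sterol, 0.207 for fatty acid oxidation, 0.156 for bile acid, 0.156 for stellate cell, 0.106 for adipose and 0.0787 for Kupffer cell genes. Without refed control replicate 2 it was 0.0849 for fatty acid oxidation, 0.0849 for cholangiocyte and 0.0623 for endothelial genes, without fasted control replicate 1 0.157 for sterol, 0.0501 for fatty acid oxidation and 0.0692 for Kupffer cell genes, without fasted control replicate 2 0.171 for fatty acid oxidation, 0.171 for cholangiocyte, 0.114 for endothelial and 0.158 for adipose genes, without fasted control replicate 3 0.176 for bile acid, 0.0834 for cholangiocyte and 0.456 for Kupffer cell genes, and without refed knockout replicate 2 0.0559 for Kupffer cell genes.

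Refed against fasted knockout livers shows the response to food without hepatocyte FoxO factors. No gene passed limma's test: 0 were called, 1751 had an unadjusted p under 0.05, 14.1% of genes did not overlap against 10% from chance, and the smallest adjusted p was 0.227. Cyp8b1 was at -2.20 (adjusted p = 0.248), Apom at -1.64 (adjusted p = 0.231), Pck1 at -0.10 and Fasn at 0.15. By camera 0 of the 35 lists passed, with a smallest adjusted p of 0.0583, and fry passed 0 in its 1-direction form. In its mixed form, which counts changes either way, fry passed 2, the insulin and growth hormone signalling list (adjusted p = 0.000495) and the FoxO-driven list (adjusted p = 0.0172). For refeeding in control livers, fry passed 0 lists in its 1-direction form and 6 in its mixed form, so such calls are not particular to knockout livers. The response of all genes in knockout livers was 0.811 times that in control livers, a ratio with no test that ran from 0.577 without refed knockout replicate 1 to 1.39 without fasted control replicate 1. Without fasted knockout replicate 3 the count was 1.

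Whether the response to food differed between genotypes was tested as an interaction. Sterol synthesis genes differed as a set, with a median difference of 0.47 and 16 of 18 positive (adjusted p = 0.000275, and adjusted p = 0.87 with an estimated correlation), their medians being -0.46 in control and 0.08 in knockout livers. Fatty acid oxidation genes had a median difference of -0.28, with 21 of 23 negative (adjusted p = 0.0306, and adjusted p = 0.87 with an estimated correlation). By limma 0 genes passed, 844 had an unadjusted p under 0.05, and fry passed 0 lists. Sqle was at 1.21 ± 0.99 (adjusted p = 0.875), G6pc at 0.90 (adjusted p = 0.842) and Fasn at 0.53 (adjusted p = 0.873). The sterol call was lost without fasted control replicate 1 (adjusted p = 0.0744), refed control replicate 3 (0.0655) or fasted knockout replicate 2 (0.0802), and the fatty acid oxidation call without fasted control replicate 2 (0.121), refed control replicates 2 (0.0628) or 3 (0.0742), fasted knockout replicate 1 (0.145) or refed knockout replicates 1 (0.0623) or 3 (0.0733). Without fasted knockout replicate 3 or refed control replicate 1 the gene count was 1.

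**Figure D3:**
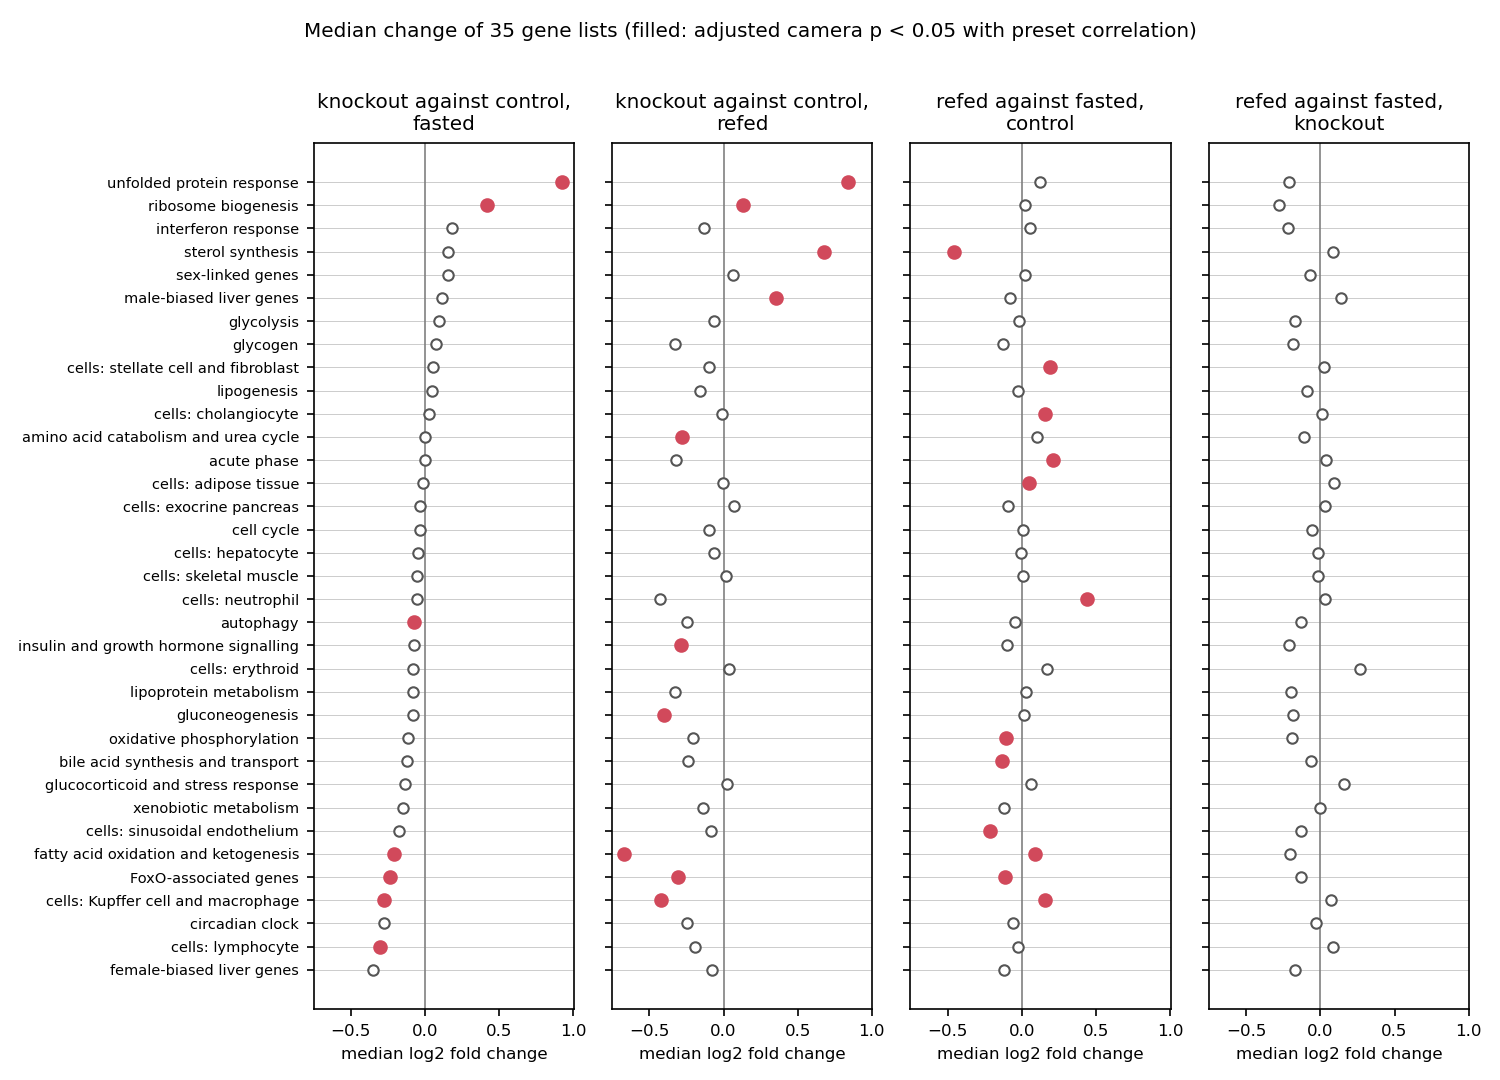
Median log2 change of each of 35 gene lists in 4 comparisons, with 1 point per list and comparison, filled where camera at a preset correlation passed after adjustment. The unfolded protein response lies at 0.92 and 0.84 in the genotype comparisons and fatty acid oxidation at -0.21 and -0.67.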

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

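Tests chosen after the result was seen were those of hepatocyte genes, of immediate early genes, of the refeeding counts without refed knockout replicate 1, of the genotype counts as a measure of power, and all use of the clock index and of averaged comparisons except the bound on the clock covariate. The power test first rested on simulation, and the 2-SE margin in the immediate early test was added after its values were known, which left it undecided. The hepatocyte test first used 12 markers, whose mean signal of 13.4 lies near the top of the range, and was replaced for that reason. The test of correlated genes was set out together with the first fit.

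The interaction for sterol synthesis genes stood out because the genotypes differed in their response to food, with an adjusted p of 0.000275. This could rest on a few arrays and on genes that move together: the highest adjusted p without 1 array was 0.0802, without fasted knockout replicate 2, and also 0.0744 without fasted control replicate 1 and 0.0655 without refed control replicate 3. With a correlation estimated from the arrays the unadjusted camera p was 0.229. Both of these are what such explanations predict, but neither can decide. Camera with an estimated correlation passed 0 lists in each comparison after adjustment. A fit without 1 array has a smaller group, so a true difference could lose its call as well. A biological difference in sterol synthesis between genotypes stays open as an untested hypothesis. The interaction for fatty acid oxidation and ketogenesis genes stood out by the same difference between genotypes, with an adjusted p of 0.0306 by camera. It kept the call in 6 of the 12 fits without 1 array, with a highest adjusted p of 0.145 without fasted knockout replicate 1. With a correlation estimated from the arrays this list did not pass after adjustment.

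Signals appeared among the 7310 transcript clusters without a gene symbol, which the comparisons of genes do not use. In fasted knockout against control livers 5 such clusters were higher and 0 lower by limma, against 0 called in refed livers and, averaged over feeding, 78 higher and 12 lower. The cluster 5431665 was higher by 3.15 ± 0.46 log2 units and the cluster 5290250 by 1.63 ± 0.24 (adjusted p = 0.0401 each), both chosen after their values were seen.

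Unfolded protein response genes were higher in knockout livers of both feeding states, with a median of 0.91 averaged over the states. A loss of other cells, leaving more hepatocyte RNA, goes with the lower Kupffer cell list (median -0.29, adjusted p = 0.628 by camera with an estimated correlation). As the whole cause it would raise other hepatocyte genes by a like amount. The 58 genes of hepatocyte functions with a mean signal between 8 and 12 had a median of -0.323 (SD 0.40 over genes). They came from 5 lists, and those of fatty acid oxidation and glucose production were already known to be lower in knockout livers. Such a fall could hide a rise from a loss of other cells, so these genes cannot decide it. A different time of sampling may contribute: with the clock index as a covariate the mean of the list differed by 0.71 ± 0.17 (SE) against 1.05 ± 0.16 without, and 0.71 less 2 SE is 0.36, under the bound of 0.52, so the share that goes with the clock is open. The index itself differed between genotypes, so the covariate cannot tell sampling time from an effect of the deletion on the clock genes. A stress from handling is also open. The median of 5 immediate early genes was 0.20, and the genotype difference in their mean over the arrays had an SE of 0.39. Among them Fos was at 0.59 (adjusted p = 0.577 by limma). The cytosolic chaperone gene Hsph1 was called higher in both feeding states, but a single gene does not decide this. An effect of the genotype on protein folding in hepatocytes stays open as an untested hypothesis, since the labels give no times.

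Few genes passed between refed and fasted livers in either genotype, and Pck1, Igfbp1 and Srebf1, which food and insulin are known to regulate, stood at 0.01, -0.12 and 0.01 in controls. If the response to food were large, an exchange of feeding labels between 1 pair of arrays would, once undone, give many calls. The highest of the 18 exchanges within a genotype gave 4. With 3 arrays a group, exchanges of 2 pairs make the same splits, so this argues against both only for a large response. A spread inflated by refed knockout replicate 1 would give many calls without it, and the larger count was 8. Too few arrays would limit every comparison, yet the lower of the genotype counts, from groups of the same size in the same fit, was 209, which speaks only to changes as large as those of genotype. Feeding times other than the labels give were not tested and stay open, as does the hypothesis of a response to food at 4 h that is small or differs between mice.

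Other splits of the arrays were counted for each comparison. For knockout against control, 1 of the 10 splits of the 6 fasted arrays gave as many genes, the real split with 209 against 0 at most in the others, and 1 of 10 in refed livers, with 235 against 1. In refed against fasted control livers 1 of 10 gave as many, with 4 against 0, and in knockout livers 10 of 10, with 0 against 4. These splits are too few for a share under 0.05, and any split matches a count of 0. For the interaction 100 of 100 regroupings gave at least the real 0, as any must, so this says nothing for or against chance, and the highest, 1093, came from a regrouping that turns the genotype difference into the interaction, a structure of the samples. For genotype averaged over feeding, 1 of 100 gave as many (1093 against 2), and for feeding averaged over genotype 1 of 100 (37 against 1). These are the smallest shares that 100 regroupings can give, which argues against chance without excluding it. Both comparisons were added after the data were seen. Another difference between samples that runs with genotype or feeding would give the same shares.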

How the results depend on the processing

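The clock covariate and the averaged comparisons were chosen after the data were seen. The clock index itself differed between genotypes, so a lower count with it does not show an effect of sampling time. No paired analysis was possible because the labels name no pairs. The number series of the titles, whose meaning is not given, served as a random block instead (6 blocks, correlation 0.116). Each block held a single genotype, so this setting cannot separate a cohort from genotype. The cause of a change was not tested unless stated. Fasted knockout against control gave 370 genes with array weights, 60 with the clock covariate, 76 with a 2-fold minimum and 63 at an adjusted p under 0.01, the last pair stricter by construction. Refed knockout against control gave 357 and 403 with the filters at the 30th and 50th percentile, 385 after quantile normalization, 18 with the compared groups alone, 154 with trend and robust moderation, 1620 with array weights, 128 with the title block, 11 with the clock covariate, 63 with a 2-fold minimum and 15 at 0.01. Refeeding in control livers gave 14 and 12 with the filters, 12 with equal medians, 8 after quantile normalization, 17 with array weights, 14 with the title block, 10 with the clock covariate and 0 at 0.01 (limma, 822 unadjusted). Refeeding in knockout livers gave 1 with the clock covariate. Genotype averaged over feeding, 1093 genes, gave 2183 with array weights, 691 with the title block, 92 with the clock covariate, 94 with a 2-fold minimum and 269 at 0.01. Feeding averaged over genotype, 37 genes, gave 60 with the 50th percentile filter, 79 with array weights, 19 with a 2-fold minimum and 0 at 0.01 (limma, 1478 unadjusted). Array weights favour the arrays nearest their group, and refed knockout replicate 1 had 0.33.

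Without each array in turn, the counts ran from 82 to 317 for fasted and 14 to 1074 for refed knockout against control, 0 to 8 and 0 to 1 for refeeding in control and knockout livers, 0 to 1 for the interaction, 544 to 1578 for genotype averaged and 4 to 39 for feeding averaged. The ratio of genotype effects ran from 0.944 to 1.22 and that of refeeding responses from 0.577 to 1.39. The balance of directions moved with scaling: fasted livers had 157 higher and 52 lower as deposited, 82 lower of 251 with equal medians and 181 higher and 131 lower after quantile normalization, and refed livers 67 and 168, then 95 and 192, then 154 and 231. The median change of all genes moved by under 0.1. The interferon response list, with medians of -0.14 in refed knockout against control and 0.05 for refeeding in controls and no call by limma's camera, changed sign without refed control replicate 2, to 0.19 (adjusted p = 0.0407 by limma's camera) and -0.22 (adjusted p = 0.00703 by limma's camera). Without each array its medians ran from -0.34 to 0.19 and from -0.22 to 0.21.

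All named calls kept their sign in each alternative: 24 of 24 genes in fasted and 32 of 32 in refed knockout against control. Of these, 12 and 2 were called in each setting other than leaving out arrays, and 12 and 3 without each array. For genotype averaged these were 16 and 31 of 59, and for feeding averaged 12 and 2 of 22. Of lists, 6 of 7 and 5 of 10 were called in each setting that kept the test, and 5 and 4 without each array. Signal near background limits the 39.2% of clusters with a mean under 5 log2 units.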

Other observations

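The averaged comparisons below, and the genes named from them, were chosen after the data were seen.

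Averaged over feeding states, the list of glucose production was lower in knockout livers, with a median of -0.31 over 14 genes, 1 of them called (adjusted p = 0.016, and adjusted p = 0.628 with an estimated correlation). Lipogenic genes went both ways, with a median of -0.05, a mean of 0.10, 5 of 24 called higher and 1 lower (adjusted p = 0.375). Igfbp1 was 3.16-fold lower (-1.66 ± 0.41, SE, 6 arrays per genotype, adjusted p = 0.0326 by limma) and Pck1 1.87-fold lower (-0.90 ± 0.23, adjusted p = 0.0411). The sterol exporter genes Abcg5 and Abcg8, which pump cholesterol into bile, were 1.95-fold (-0.96 ± 0.18, adjusted p = 0.0115) and 2.48-fold lower (-1.31 ± 0.22, adjusted p = 0.00611). Fasn rose 2.24-fold (1.16 ± 0.21, adjusted p = 0.00915), Elovl6 3.18-fold (1.67 ± 0.17) and Acly, which makes cytosolic acetyl-CoA, by 0.60 (adjusted p = 0.0384). Cpt1a, the gate of fatty acid entry into mitochondria, fell by 0.57 (adjusted p = 0.018) and Pdk4, which spares glucose from oxidation, fell by 0.95 (adjusted p = 0.0323). Mt1, a metal-binding protein gene, was 4.05-fold lower (-2.02 ± 0.42, adjusted p = 0.0165), and Cyp26a1, which degrades retinoic acid, 4.14-fold higher (2.05 ± 0.51, adjusted p = 0.0352). Of 1093 called genes 459 were higher and 634 lower. With the clock index as a covariate 57 were higher and 35 lower, 92 in all, and of the 13 genes named here Elovl6 and Mt1 kept the call. The fatty acid oxidation list had a median of -0.41 with 7 of 23 genes called (adjusted p = 1.22e-08, and adjusted p = 0.628 with an estimated correlation), and the FoxO-driven list -0.32 with 11 of 32 called (adjusted p = 6.41e-05, and adjusted p = 0.548 with an estimated correlation). The Kupffer cell list had a median of -0.29 (adjusted p = 0.00277, and adjusted p = 0.628 with an estimated correlation), with the macrophage protein gene Cd5l at -0.61 ± 0.14 (adjusted p = 0.0275), and the B-cell receptor gene Cd79b at -1.06 ± 0.23 (adjusted p = 0.0197). Without single arrays the count was 675 without fasted control replicate 3, 724 and 637 without fasted knockout replicates 2 and 3, 696 and 626 without refed control replicates 2 and 3, and 544 without refed knockout replicate 3. Higher genes outnumbered lower ones without fasted control replicate 2 (401 and 328), fasted knockout replicate 2 (375 and 349) and refed control replicate 2 (358 and 338). Without each array in turn Abcg5, Abcg8, Fasn, Elovl6 and Mt1 stayed called. Cpt1a reached an adjusted p of 0.0504 without refed knockout replicate 3 and Cd79b 0.0521 without refed control replicate 3. The highest adjusted p was 0.0789 for Igfbp1 without refed knockout replicate 3, 0.0888 for Pck1 without fasted control replicate 2, 0.0913 for Acly and 0.0664 for Cd5l without fasted knockout replicate 3, and 0.0787 for Pdk4 and 0.0859 for Cyp26a1 without refed control replicate 3, and these 6 lost the call without several other arrays too.

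Averaged over genotypes, 37 genes differed between refed and fasted livers, 16 higher and 21 lower. Cyp8b1, which sets the balance of bile acids, was 5.91-fold lower (-2.56 ± 0.38, SE, 6 arrays per feeding state, adjusted p = 0.029 by limma), Igfbp2, a binding protein for growth factors, 5.46-fold lower (-2.45 ± 0.31, adjusted p = 0.022) and Apom 3.55-fold lower (-1.83 ± 0.22, adjusted p = 0.0172). Foxo1 itself was 1.58-fold lower (-0.66 ± 0.10, adjusted p = 0.029). This average includes knockout livers, where Foxo1 was deleted in hepatocytes, and Foxo1 was not among the 4 genes called in control livers alone. The lipid droplet gene Plin4 rose 2.68-fold (1.42 ± 0.21, adjusted p = 0.029) and Elovl3, another fatty acid elongase, 3.04-fold (1.60 ± 0.26, adjusted p = 0.0366). Of 22 genes named by the rule, 2 stayed called without each array in turn, and none of these 6 did. Apom lost the call without fasted control replicate 2 and fasted knockout replicate 1 (highest adjusted p = 0.0618) and Igfbp2 without those and fasted knockout replicate 2 (highest 0.0755). The highest adjusted p was 0.0828 for Cyp8b1 and Plin4 without fasted knockout replicate 2 and 0.0865 for Foxo1 and 0.0954 for Elovl3 without refed control replicate 3, and these 4 lost the call without several other arrays too. The count was 11, 6 and 14 without fasted control replicates 1, 2 and 3, 4 and 5 without fasted knockout replicates 1 and 2, 22 and 12 without refed control replicates 2 and 3, and 12 without refed knockout replicate 1.

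In control livers refed replicate 1 carried an Ngp signal, a neutrophil granule gene, of 8.53, against 3.76 and 3.40 in the other refed control arrays. Asns, which makes asparagine and responds to amino acid supply, was at 3.55 ± 0.59 in refed against fasted control livers without passing (adjusted p = 0.0796). Both were chosen after their values were seen. Arrays of different groups whose titles share a number series had a mean correlation of 0.15 between their deviations from the group means over 6 pairs, against -0.02 over 48 other pairs. The labels do not say what the numbers mean. Each series held arrays of a single genotype, so the sharing pairs were all within a genotype while other pairs also crossed genotypes. Between control and knockout arrays, a cohort behind the numbers cannot be told apart from genotype. Within the knockout arrays the series can be compared. Fasted replicate 3 and refed replicates 2 and 3 share a series, and their clock indices were -1.25, -2.05 and -1.24. In the other knockout arrays, fasted replicates 1 and 2 and refed replicate 1, they were -3.08, -2.69 and -2.37. Control arrays lay from -3.49 to -2.23. This difference between series was seen afterwards and was not tested.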
